A study of Homo sapiens with 6 samples.

How the data were processed

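Poly(A) RNA of KYSE70 cells with a doxycycline-inducible hairpin against SOX2 or TP63 was sequenced in 6 libraries, 1 per line at day 0 and 2 per line at day 4. Per the labels' protocols, poly(A) RNA was isolated with oligo(dT) beads, fragmented, reverse transcribed with random primers, made into libraries with a DNA library kit and sequenced on an Illumina HiSeq instrument. No strand-specific step is stated, so a gene and its antisense partner may share reads. The deposited table names its values as RPKM. The values themselves fit a log of RPKM + 1, and base 2 was assumed, because the features given next do not show the base. The lowest value is 0, and all 6 libraries share a highest value of 13.36. Of the values above 0, 82.9% are multiples of 1/7000 within a tolerance of 0.01 of a step, and 100% are multiples of 1/14000. Such steps arise when log values of 3 decimals are averaged over 7 columns, so the deposited log2 values were treated as quantile-normalized between libraries by the authors. This is read from the values, and what the seventh column held is not given in the sources used here. The design fixed beforehand assumed RPKM, and the deposited log2 values were therefore tested directly, without a further log. Linear values for filters were taken as 2 to the power of the value, minus 1. The genome build was hg19, per the submitters' processing notes. The aligner, the counter and the annotation are not given in the sources used here. No coordinates are printed, because the annotation used here was of another build and served only for gene names and for the place of MIR711 within COL7A1.

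The table held 48644 gene rows with no repeated name. Depth cannot be recovered, because quantile normalization removes it. The number of genes above 0 was 16167 in the uninduced shTP63 library and 21530 to 23509 in the others, and 56 of the tested genes were at 0 in that library against 0 to 5 in each other library. At most 0.12% of the tested genes had exactly equal values in any 2 libraries, so no library was an exact copy of another. Between libraries the Pearson correlation across tested genes was 0.858 to 0.941, and 0.941 for both day 4 pairs. The uninduced libraries of the different lines correlated at 0.939. With the induced libraries of its own line, day 0 correlated at 0.903 and 0.924 for shSOX2 and at 0.89 and 0.892 for shTP63.

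Genes with a mean linear RPKM of at least 1 over the 6 libraries were kept, which left 10536. The numbers in parentheses in the sample titles were taken as replicate numbers; they could also number hairpins. limma 3.58.1 in R 4.3.3 was fitted with 4 group means on all 6 libraries, with a mean-variance trend, 2 residual degrees of freedom and about 5.5 prior degrees of freedom. Contrasts were day 4 against day 0 in each line, the difference of those responses, and the induced lines against each other. P-values are two-sided, adjusted after Benjamini and Hochberg, with a call at an adjusted p under 0.05. Errors after ± are standard errors from limma. A separate rule of size counted genes at least 2-fold apart from day 0 the same way in both day 4 libraries. No group has 3 libraries, so no other splits of the samples were counted.

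The 25 gene lists were fixed before the data were examined, as were the tests and the alternatives except where the text says otherwise. They were squamous transcription factors, basal keratinocyte and hemidesmosome genes, desmosome and adherens junction, squamous differentiation, columnar and glandular epithelium, mesenchymal genes, leukocyte and endothelial markers, G2 and M phase, G1/S and DNA replication, p53 response, type I interferon response, NF-kB and inflammatory cytokines, Notch, Wnt, receptor tyrosine kinase and ERK feedback, TGF-beta and BMP response, integrated stress response, cholesterol biosynthesis, glycolysis, NRF2 and glutathione, reported TP63 targets in keratinocytes, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, replication-dependent histones and cytosolic ribosomal proteins. The 24 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. With an estimated correlation 0 lists passed in any contrast, and fry's directional test passed 0. The test of fry for change in either direction passed 6 lists in the shSOX2 line, 8 in the shTP63 line and 0 for the difference. Counts of members "adjusted over the list alone" use the Benjamini-Hochberg adjustment within a list. The list of squamous transcription factors holds SOX2 and TP63, the hairpin targets themselves.

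The genes named were set by a rule fixed before the data were examined. SOX2 and TP63 are always named. For each induction the 10 largest changes per direction among called genes that moved the same way in both day 4 libraries are named, filled from genes changed at least 1.5-fold the same way in both, in order of unadjusted p, and said not to pass. For the other contrasts 5 per direction are named by the same rule, and for lists members among the 4 with the smallest unadjusted p. Genes without a symbol were skipped, and 9427 of the 10536 tested genes had one in RefSeq or GENCODE. GENCODE symbols were added after the values were seen, because RefSeq writes the mitochondrial genes without the MT- prefix and they had been skipped in error. This brought in MT-ND5 and MT-ND6 between the induced lines. COL7A1 and the genes listed after the list tests in the closing part were named after their values were seen.

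The scripts were tested on simulated data with the spread of these libraries, in 10 runs of 10536 genes with 200 changed. The changed genes were drawn only from genes with a higher mean value, so the rates do not cover low genes. For SOX2 hairpin induction limma recovered 0.6% of changes of 1 log2 unit, 33.8% of 2 units and 90.8% of 3 units. For TP63 hairpin induction it recovered 1.2%, 41.2% and 90.2%, and between the induced lines 3.2%, 69.6% and 97.6%. In these runs a mean of 5.5, 5.1 and 6.1 unchanged genes was called, in the same order. With no changed genes the mean count was 0 for both inductions and the induced lines, and 0.1 for the difference. A list lowered by 0.8 log2 units was called in 10 of 10 runs by camera with the preset correlation and in 0 with an estimated correlation. The simulated genes varied independently, so these runs cannot show how either setting fares when list members move together. Alternatives changed the pseudocount to 0.1 or 5, the filter to none or to a mean RPKM of at least 5, the scaling, the trend, the control libraries and the set of libraries, and fitted the replicate number as a block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.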

Results

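The series measured poly(A) RNA in KYSE70, an established human esophageal squamous carcinoma cell line, carrying a doxycycline-inducible hairpin against either SOX2 or TP63. Both genes encode transcription factors of squamous and basal epithelium. There were 6 libraries in 4 groups. Each hairpin line had 1 library at day 0, before doxycycline, and 2 libraries at day 4, after doxycycline at 50 ng/ml. The titles number the libraries, and the numbers were taken as replicates but could stand for different hairpins against the same gene. In that case the day 4 libraries numbered 1 would have no day 0 library of their own. The design asks which genes respond when either factor is suppressed. The values were read as log2(RPKM + 1), with base 2 assumed, so a log2 change understates the change of low genes. The read depth is unknown, because the values hold no counts. The uninduced shTP63 library had 16167 genes above 0 and a smallest value above 0 of 0.143, while the other 5 libraries had 21530 to 23509 genes above 0. It is the only library of its group, so its values enter every statement on TP63 hairpin induction. A lone day 0 library was assumed to vary like the day 4 pairs. The labels do not say that the libraries came from separate cultures, so limma and fry p-values measure only the spread between these samples, which may be technical. Camera p-values with the preset correlation compare list members with the other genes and treat the members as nearly independent. They do not measure the spread between samples, however small they are.

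SOX2 was at 6.25 in the uninduced shSOX2 library and at 5.65 and 4.67 in the induced libraries of that line, a log2 change of -1.10 ± 0.45 (limma SE, day 4 n = 2, day 0 n = 1, adjusted p = 0.469). In the shTP63 line SOX2 was at 5.69 before induction and at 5.55 and 5.41 after it. TP63 was at 3.99 in the uninduced shTP63 library and at 2.26 and 2.11 in the induced ones, a log2 change of -1.81 ± 0.32 (limma adjusted p = 0.131). In the shSOX2 line TP63 was at 3.61 before induction and at 3.91 and 3.93 after it, a log2 change of 0.31 ± 0.32 (limma adjusted p = 0.749). Each target was thus lower in both induced libraries of its own line, and neither change passed the test over all genes against its own day 0 library. For SOX2 the log2 difference between the induced lines, shTP63 minus shSOX2, was 0.32 ± 0.37 and did not pass (limma adjusted p = 0.621). Induced shSOX2 replicate 2, at 5.65, was above both induced shTP63 libraries, so its SOX2 was not lower than in the other line. Between the induced lines TP63 was lower with the TP63 hairpin by a log2 difference of -1.73 ± 0.26, which passed (limma adjusted p = 0.0467). That call was lost without either shSOX2 day 4 library and without shTP63 day 4 replicate 2. It was also lost with a pseudocount of 5 (limma adjusted p = 0.0624), with no filter (0.286) and with the replicate number as a block. In a setting chosen after seeing the data, without mitochondrial, structural RNA and histone genes, it was lost too (0.0539). The log2 difference of TP63 ranged from -1.96 to -1.16 over these and the other alternatives. Its adjusted p ranged from 0.0382 to 0.286 over 13 alternatives, and that of TP63 against its own day 0 library from 0.0248 to 0.229, passing only with both day 0 libraries as the control (log2 change -1.61, limma adjusted p = 0.0248).

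**Figure D1:**
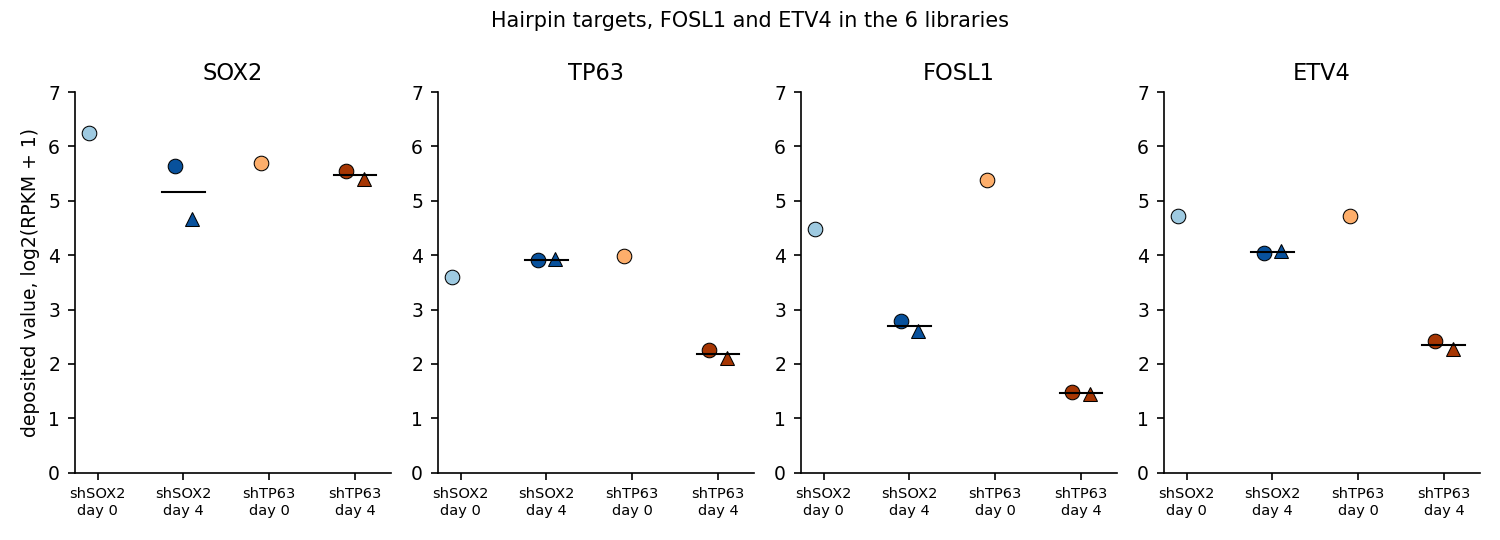
Deposited values, on the log2(RPKM + 1) scale of the y axis, of SOX2, TP63, FOSL1 and ETV4 in the 6 libraries, by hairpin line and day on the x axis. Circles are replicate 2, triangles replicate 1, and bars the mean of 2 libraries. TP63 lay at 2.26 and 2.11 in the induced shTP63 libraries and between 3.61 and 3.99 in the other 4, and FOSL1 lay at 1.48 and 1.45 in the induced shTP63 libraries and at 5.38 before induction.

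After induction of the SOX2 hairpin, the genes with the smallest p on the lower side were SPRR3, a cornified envelope precursor, with a log2 change of -2.69 ± 0.26, CNN1, an actin-binding calponin, with -2.25 ± 0.29, and the small GTPase gene RASL11A with -2.37 ± 0.32. On the higher side they were the tetraspanin gene TSPAN7 with a log2 change of 3.19 ± 0.42, the complement protease gene C1S with 2.42 ± 0.32, and CA11, a carbonic anhydrase-related gene, with 2.34 ± 0.35. HK2, which encodes a hexokinase of glycolysis, had a log2 change of -2.05 ± 0.36, the AP-1 subunit gene FOSL1 one of -1.79 ± 0.32, and SOX21 one of -1.83 ± 0.34. SCD, the stearoyl-CoA desaturase gene, had a log2 change of 2.15 ± 0.38, and the ligand gene BMP4 one of 1.94 ± 0.35. All of these moved the same way in both day 4 libraries. None passed the test: limma called 0 of 10536 genes, the smallest adjusted p was 0.106, for SPRR3, and 1094 genes had an unadjusted p under 0.05 against 527 expected.

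The other genes that the naming rule gave on the higher side were IFITM1 at a log2 change of 2.28, C1R at 2.66, MAFA at 1.77, the syndecan gene SDC4 at 1.89 and the semaphorin gene SEMA3C at 1.82. On the lower side they were CTSL2 at -2.38, the neuropilin gene NRP2 at -1.88, C8orf4 at -1.82 and KRT6A at -2.73. The uninduced shTP63 library differed from the uninduced shSOX2 library by -2.15 for CTSL2, -1.58 for SPRR3, -1.17 for RASL11A and 1.31 for IFITM1. CTSL2 stood at 5 there, against 4.99 and 4.56 in the induced shSOX2 libraries. The size of these changes thus depends on 1 library, while C1S and CNN1 differed by 0.22 and -0.26. KRT6A shares long stretches with other keratin 6 genes, and IFITM1 with other IFITM genes, so their values are uncertain. By size alone, 365 genes were at least 2-fold apart from day 0 the same way in both induced libraries, 261 higher and 104 lower. Simulated libraries with no effect, where day 0 varied like the day 4 pairs, gave a mean of 149 such genes. Single pairs of libraries, a looser count, held 487 genes at least 2-fold apart between the uninduced ones and 514 between the 2 induced ones. By the rule of size the count was 748 without shSOX2 day 4 replicate 2 and 1104 without shSOX2 day 4 replicate 1. Against the day 0 library of the other line it was 878. With the 3 libraries of this line alone limma called 11 genes, 5 higher and 6 lower. Leaving out either shTP63 day 4 library moved the count as well, through the estimate of the spread alone, since the log2 changes do not use that library. Limma called 2 genes with both day 0 libraries as the control.

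Of the 24 gene lists tested in the shSOX2 line, 8 passed camera with a preset correlation, 3 lower and 5 higher. The 35 genes of G1/S and DNA replication fell, with a median log2 change of -0.72 (camera adjusted p = 4.95e-11, adjusted p = 0.52 with an estimated correlation). Of these, 31 were lower in both induced libraries. UHRF1, a maintenance factor of DNA methylation, had a log2 change of -1.55 ± 0.34, the cyclin gene CCNE2 one of -1.20 ± 0.27, the checkpoint mediator gene CLSPN one of -1.23 ± 0.31 and the replication licensing gene CDC6 one of -1.36 ± 0.34. 0 of the 35 passed over all genes, and 4 were lower when adjusted over the list alone. The 23 replication-dependent histone genes fell as a list (median -0.64, camera adjusted p = 0.000118, adjusted p = 0.52 with an estimated correlation), with HIST1H4C at -1.04 ± 0.35, and 0 of 23 passed over all genes or adjusted over the list alone. Histone genes resemble one another, so single members are uncertain. Glycolysis genes fell (median -0.48 over 21 genes, camera adjusted p = 0.00719, adjusted p = 0.52 with an estimated correlation). HK2 was the 1 member lower when adjusted over the list alone, GAPDH had a log2 change of -1.21 ± 0.55 (-1.94 in replicate 2 and -0.47 in replicate 1), and 0 passed over all genes. The glycolysis median was -0.52 in replicate 2 and -0.27 in replicate 1, and that of histones -0.40 and -0.98.

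Among the lists that rose in the shSOX2 line, the integrated stress response had a median log2 change of 0.50 over 33 genes (camera adjusted p = 0.000192, adjusted p = 0.52 with an estimated correlation). Its members DDIT4, an inhibitor of mTORC1, at 1.82 ± 0.35, VEGFA at 1.20 ± 0.34 and NUPR1 at 2.25 ± 0.64 were higher, 1 member passed when adjusted over the list alone and 0 over all genes. TGF-beta and BMP response genes rose (median 0.37 over 19 genes, camera adjusted p = 0.0028, adjusted p = 0.52 with an estimated correlation), led by BMP4 and by BMP7 at 1.24 ± 0.34. In that list 1 gene was higher when adjusted over the list alone and 0 over all genes. NF-kB and inflammatory cytokine genes rose (median 0.44 over 15 genes, camera adjusted p = 0.00474, adjusted p = 0.52 with an estimated correlation). In it the chemokine gene CCL2 was at 2.64 ± 0.59 and SAA1 at 3.25 ± 0.93 (4.63 in replicate 2 and 1.88 in replicate 1), with 1 gene higher when adjusted over the list alone and 0 over all genes. SAA1 stood at 1.07 in the uninduced shSOX2 library and at 4.06 in the uninduced shTP63 library. The size of its change thus depends on the control. Wnt pathway genes rose (median 0.46 over 14 genes, camera adjusted p = 0.00719, adjusted p = 0.52 with an estimated correlation), with LGR4 at 1.18 ± 0.29 and WNT5A at 1.40 ± 0.35, 2 genes higher when adjusted over the list alone and 0 over all genes. Cholesterol biosynthesis genes rose (median 0.45 over 23 genes, camera adjusted p = 0.0103, adjusted p = 0.52 with an estimated correlation), with INSIG1 at 1.46 ± 0.36 and 0 members passing either over all genes or when adjusted over the list alone. In replicate 2 and replicate 1 the medians were 0.80 and 0.18 for the integrated stress response and 0.29 and 0.45 for cholesterol biosynthesis. Without shSOX2 day 4 replicate 2 the calls of the integrated stress response (camera adjusted p = 0.0719) and glycolysis (0.0679) were lost, and without shSOX2 day 4 replicate 1 those of cholesterol biosynthesis (0.108) and histones (0.108). With both day 0 libraries as the control the calls of NF-kB (0.306) and TGF-beta and BMP (0.0503) were lost, and at a mean RPKM of at least 5 those of NF-kB (0.166), Wnt (0.0583) and glycolysis (0.0557).

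The remaining lists did not pass camera in the shSOX2 line. For change in either direction, fry passed squamous differentiation, columnar epithelium, the p53 response, receptor tyrosine kinase and ERK feedback and reported TP63 targets, and also Wnt (fry mixed adjusted p = 0.032 for each). Their median log2 changes were -0.17 for squamous transcription factors (camera adjusted p = 0.251), 0.10 for basal keratinocyte and hemidesmosome genes (0.067), 0.15 for desmosome and adherens junction genes (0.283), 0.12 for squamous differentiation (0.204), -0.27 for columnar and glandular epithelium (0.0555), 0.50 for mesenchymal genes (0.0555), -0.19 for G2 and M phase (0.142) and 0.10 for the p53 response (0.208). They were 0.13 for the type I interferon response (0.067), 0.13 for the Notch pathway (0.361), 0.23 for receptor tyrosine kinase and ERK feedback (0.512), 0.18 for NRF2 and glutathione (0.0555), 0.14 for reported TP63 targets in keratinocytes (0.537), -0.21 for mitochondrially encoded genes (0.0964), -0.04 for nuclear-encoded oxidative phosphorylation (0.851) and -0.09 for cytosolic ribosomal proteins (0.267). Squamous differentiation had a mean of -0.48 against its median of 0.12 and a test on the lower side. Its members SPRR3, KRT6A and KRT6B, the last at -2.60 ± 0.55, were the 3 lower ones when adjusted over the list alone, and KRT13, a mucosal keratin gene, had a log2 change of 0.96 ± 0.40. Nuclear-encoded oxidative phosphorylation had a test on the higher side against its negative median. Over all genes 0 members of these lists passed. When adjusted over the list alone 2 were lower among columnar keratin genes, where KRT8 was at -1.61 ± 0.32 and KRT18 at -1.51 ± 0.39, and 3 were higher among mesenchymal genes, with COL5A1 at 2.15 ± 0.50 and COL3A1 at 2.79 ± 0.88 (1.54 in replicate 2 and 4.04 in replicate 1). A further 2 basal genes, PDPN at 2.17 ± 0.41 and BCAM at 2.48 ± 0.56, and 2 interferon genes were higher, and 1 kinase pathway gene and 1 reported TP63 target were lower. Without either shTP63 day 4 library 13 lists passed, those of columnar epithelium, mesenchymal genes, G2 and M phase, NRF2 and mitochondrially encoded genes being added. Without shSOX2 day 4 replicate 2 the NRF2 list passed, and without shSOX2 day 4 replicate 1 the basal and mesenchymal lists. Over all alternatives the NRF2 and mesenchymal lists each passed in 5 and columnar epithelium in 4. G2 and M phase and mitochondrially encoded genes each passed in 3, basal genes in 2 and cytosolic ribosomal proteins in 1. CD68, the 1 tested member of the leukocyte and endothelial list, had a log2 change of -0.61 ± 0.29.

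After induction of the TP63 hairpin, FOSL1 fell from 5.38 to 1.48 and 1.45, a log2 change of -3.91 ± 0.32 (limma adjusted p = 0.0317). ZNF467, a zinc finger gene, was listed at 0 in the uninduced library and stood at 3.35 and 3.78 in the induced ones (limma adjusted p = 0.0332). These 2 were the only calls of limma among 10536 genes, and 1535 genes had an unadjusted p under 0.05. ETV4, a transcription factor gene downstream of ERK signalling, had a log2 change of -2.38 ± 0.33, the keratin gene KRT75 one of -3.56 ± 0.39, and the uridine phosphorylase gene UPP1 one of -2.41 ± 0.37, none of which passed. KRT75 stood at 4.16 in the uninduced shTP63 library and at 0.46 in the uninduced shSOX2 library, so its lower value rests on 1 library. ARID5B had a log2 change of 2.37 ± 0.31, the thioredoxin inhibitor gene TXNIP one of 2.69 ± 0.37, and the folate receptor gene FOLR1 one of 3.02 ± 0.45, which did not pass either.

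Other genes that the naming rule gave here, none past the threshold, were RGAG4 at a log2 change of 2.55, the cornified envelope gene CNFN at 2.06, CA11 at 2.27, C1S at 2.07, NELL2 at 2.17 and FTLP3 at 1.93 on the higher side. On the lower side they were GNG13 at -2.15, HIST2H3D at -2.15, CD68 at -2.07, UHRF1 at -2.26, the galanin gene GAL at -2.27 and KRT6A at -3.15. The uninduced shTP63 library exceeded the uninduced shSOX2 library by 1.39 for GNG13, 1.28 for HIST2H3D, 0.97 for CD68 and 0.70 for KRT6A. The size of these falls thus depends on 1 library, while UHRF1 and GAL differed by -0.17 and -0.04. FTLP3 is a pseudogene of FTL and can share its reads. By size alone, 618 genes were at least 2-fold apart from day 0 the same way in both induced libraries, 321 higher and 297 lower, against a mean of 148 in simulated libraries with no effect. Single pairs of libraries, a looser count, held 487 genes at least 2-fold apart between the uninduced ones and 551 between the 2 induced ones. By the rule of size the split was 385 higher and 235 lower with median-ratio scaling. The count was 1214 without shTP63 day 4 replicate 2 and 1291 without shTP63 day 4 replicate 1. The calls of FOSL1 and ZNF467 were lost when either shSOX2 day 4 library was left out, with their log2 changes unmoved at -3.91 and 3.56. Those libraries enter this contrast only through the estimate of the spread. The calls were also lost with the 3 libraries of the line alone (both limma adjusted p = 0.21), which gave 0 calls. With the replicate number as a block they were lost too (0.155 and 0.156). Over the alternatives the log2 change ranged from -4.45 to -2.75 for FOSL1 and from 1.66 to 6.77 for ZNF467. With no filter limma called 154 genes, 2 higher and 152 lower, and ZNF467 was not among them (adjusted p = 0.0722). With both day 0 libraries as the control limma called 291 genes, 163 higher and 128 lower. With the uninduced shTP63 library left out and the uninduced shSOX2 library as the control, a setting chosen after seeing the data, it called 50 genes, 26 higher and 24 lower. Without shTP63 day 4 replicate 2 it called 80 genes and without shTP63 day 4 replicate 1 60 genes.

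Of the 24 lists tested in the shTP63 line, 10 passed camera with a preset correlation, 5 lower and 5 higher. All 23 replication-dependent histone genes were at least 2-fold lower in both induced libraries and the list fell (median log2 change -2.14, camera adjusted p = 1.79e-22, adjusted p = 0.64 with an estimated correlation). HIST1H4C went from 6.43 to 4.39 and 4.07, and HIST1H2AJ from 5.70 to 2.88 and 3.27. 0 of the 23 passed over all genes, and 23 were lower when adjusted over the list alone. The median of these genes was 4.83 in the uninduced shTP63 library and 3.26 in the uninduced shSOX2 library. It was 2.42 in induced shTP63 replicate 2 and 3.27 in replicate 1. With the uninduced shSOX2 library as the control the median change was -0.49, and the replicate 1 median did not lie below that control. G1/S and DNA replication genes fell (median -1.22 over 35 genes, camera adjusted p = 1.05e-18, adjusted p = 0.64 with an estimated correlation), with 33 lower in both induced libraries. CDC45, a helicase component gene, was at -1.99 ± 0.36 and MCM7 at -1.78 ± 0.35, with 23 genes lower when adjusted over the list alone and 0 over all genes. G2 and M phase genes fell (median -0.88 over 29 genes, camera adjusted p = 6.74e-07, adjusted p = 0.76 with an estimated correlation). The mitotic kinase gene AURKA was at -1.18 ± 0.35 and CDC20 at -1.69 ± 0.53 (-2.34 in replicate 2 and -1.05 in replicate 1), and 0 passed over all genes or adjusted over the list alone. The G2 and M median was -1.53 in replicate 2 and -0.22 in replicate 1, and without replicate 2 of shTP63 day 4 the call was lost (camera adjusted p = 0.0695).

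Receptor tyrosine kinase and ERK feedback genes fell in the shTP63 line (median -0.56 over 27 genes, camera adjusted p = 0.00246, adjusted p = 0.64 with an estimated correlation). FOSL1 was the 1 member that passed over all genes, and 8 were lower and 3 higher when adjusted over the list alone. SPRY4, a feedback inhibitor of the pathway, was at -1.38 ± 0.28 and the ERK phosphatase gene DUSP6 at -1.30 ± 0.29. NF-kB and inflammatory cytokine genes fell (median -0.46 over 15 genes, camera adjusted p = 0.0493, adjusted p = 0.64 with an estimated correlation), with PTGS2 at -1.30 ± 0.37, and 0 passed over all genes or adjusted over the list alone. Cholesterol biosynthesis genes rose (median 0.67 over 23 genes, camera adjusted p = 5.01e-05, adjusted p = 0.64 with an estimated correlation). INSIG1, a sterol sensor partner, was at 1.85 ± 0.36 and STARD4 at 1.78 ± 0.34, with 3 higher when adjusted over the list alone and 0 over all genes. NRF2 and glutathione genes rose (median 0.56 over 34 genes, camera adjusted p = 6.12e-05, adjusted p = 0.75 with an estimated correlation), with GSTM3 at 1.72 ± 0.36 and GPX2 at 1.34 ± 0.35, 4 higher when adjusted over the list alone and 0 over all genes. Nuclear-encoded oxidative phosphorylation genes rose (median 0.42 over 35 genes, camera adjusted p = 0.000401, adjusted p = 0.76 with an estimated correlation), with NDUFA4 at 1.85 ± 0.36, 1 higher when adjusted over the list alone and 0 over all genes. NDUFA4 stood at 3.02 in the uninduced shTP63 library and at 4.31 in the uninduced shSOX2 library, so the size of its change depends on the control. TGF-beta and BMP response genes rose (median 0.42 over 19 genes, camera adjusted p = 0.000926, adjusted p = 0.64 with an estimated correlation). BMP4 was at 1.79 ± 0.35 and ID2, an inhibitor of basic helix-loop-helix factors, at 1.93 ± 0.43, with 4 higher when adjusted over the list alone and 0 over all genes. Type I interferon response genes rose (median 0.27 over 9 genes, camera adjusted p = 0.0497, adjusted p = 0.64 with an estimated correlation), with IFITM3 at 1.56 ± 0.39, 2 higher when adjusted over the list alone and 0 over all genes. In replicate 2 and replicate 1 of shTP63 day 4 the medians were 0.84 and 0.28 for NRF2, 0.48 and 0.28 for oxidative phosphorylation, 0.54 and 0.20 for interferon and -0.80 and -0.48 for NF-kB. With the uninduced shSOX2 library as the control the calls of receptor tyrosine kinase and ERK feedback (0.0999) and cholesterol biosynthesis (0.0963) were lost and the NF-kB median was 0.18 (0.326). The interferon call was lost without each of the 4 day 4 libraries in turn and with median-ratio scaling (camera adjusted p = 0.0562), among other settings, and held in 7 of 16 alternatives. The NF-kB call was lost without shTP63 day 4 replicate 2 and with both day 0 libraries as the control (0.733), among other settings, and held in 9 of 17. With no filter the TGF-beta and BMP call was lost (0.388), and at a mean RPKM of at least 5 those of NF-kB (0.248) and receptor tyrosine kinase and ERK feedback (0.0788).

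For change in either direction in the shTP63 line, fry passed reported TP63 targets (fry mixed adjusted p = 0.0046), squamous differentiation (0.017) and, at 0.014, squamous transcription factors, desmosome and adherens junction, mesenchymal and p53 response genes, and also receptor tyrosine kinase and ERK feedback (0.0048) and TGF-beta and BMP (0.014). The lists that did not pass camera there had median log2 changes of 0.17 for squamous transcription factors (camera adjusted p = 0.963), -0.23 for basal keratinocyte and hemidesmosome genes (0.422), 0.30 for desmosome and adherens junction genes (0.128), -0.08 for squamous differentiation (0.59), 0.10 for columnar and glandular epithelium (0.966), 0.28 for mesenchymal genes (0.602) and 0.09 for the p53 response (0.647). The medians were -0.06 for the Notch pathway (0.913), 0.13 for the Wnt pathway (0.966), 0.14 for the integrated stress response (0.913), -0.14 for glycolysis (0.301), 0.14 for reported TP63 targets in keratinocytes (0.756), 0.15 for mitochondrially encoded genes (0.966) and 0.11 for cytosolic ribosomal proteins (0.313). For columnar epithelium, Wnt and the integrated stress response the median was positive and the test on the lower side, and for Notch the median was negative and the mean of 0.06 positive. Over all genes 0 members of these lists passed. CDH1, the E-cadherin gene, had a log2 change of 2.63 ± 0.52, and COL3A1, a fibrillar collagen gene, one of 4.00 ± 0.88. CDH1 stood at 1.87 in the uninduced shTP63 library and at 3.5 in the uninduced shSOX2 library, so the size of its change depends on the control. Over the alternatives the CDH1 change was as low as 0.998. CDKN1A, a cell cycle inhibitor gene, had a log2 change of 1.47 ± 0.37 and the amino acid transporter gene SLC7A5 one of -1.82 ± 0.39. When adjusted over the list alone 1 junction gene was higher, and 3 mesenchymal genes, 3 p53 response genes, 3 reported TP63 targets, 2 mitochondrial genes, 1 squamous transcription factor gene and 1 squamous differentiation gene were higher. Lower when adjusted over the list alone were 4 squamous differentiation genes, among them KRT6A and KRT6B, 2 p53 response genes, 2 mitochondrial genes and 1 gene each of the squamous transcription factors, mesenchymal genes, Wnt, glycolysis and reported TP63 targets. The lower squamous transcription factor gene was TP63, the target of the hairpin, so that count and the fry result of that list include the suppressed gene. CD68 had a log2 change of -2.07 ± 0.29. Without shTP63 day 4 replicate 2 the cytosolic ribosomal protein list passed on the higher side (median 0.32, camera adjusted p = 0.00283). With the uninduced shSOX2 library as the control the p53 response list passed on the higher side (median 0.55, camera adjusted p = 0.0115).

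**Figure D2:**
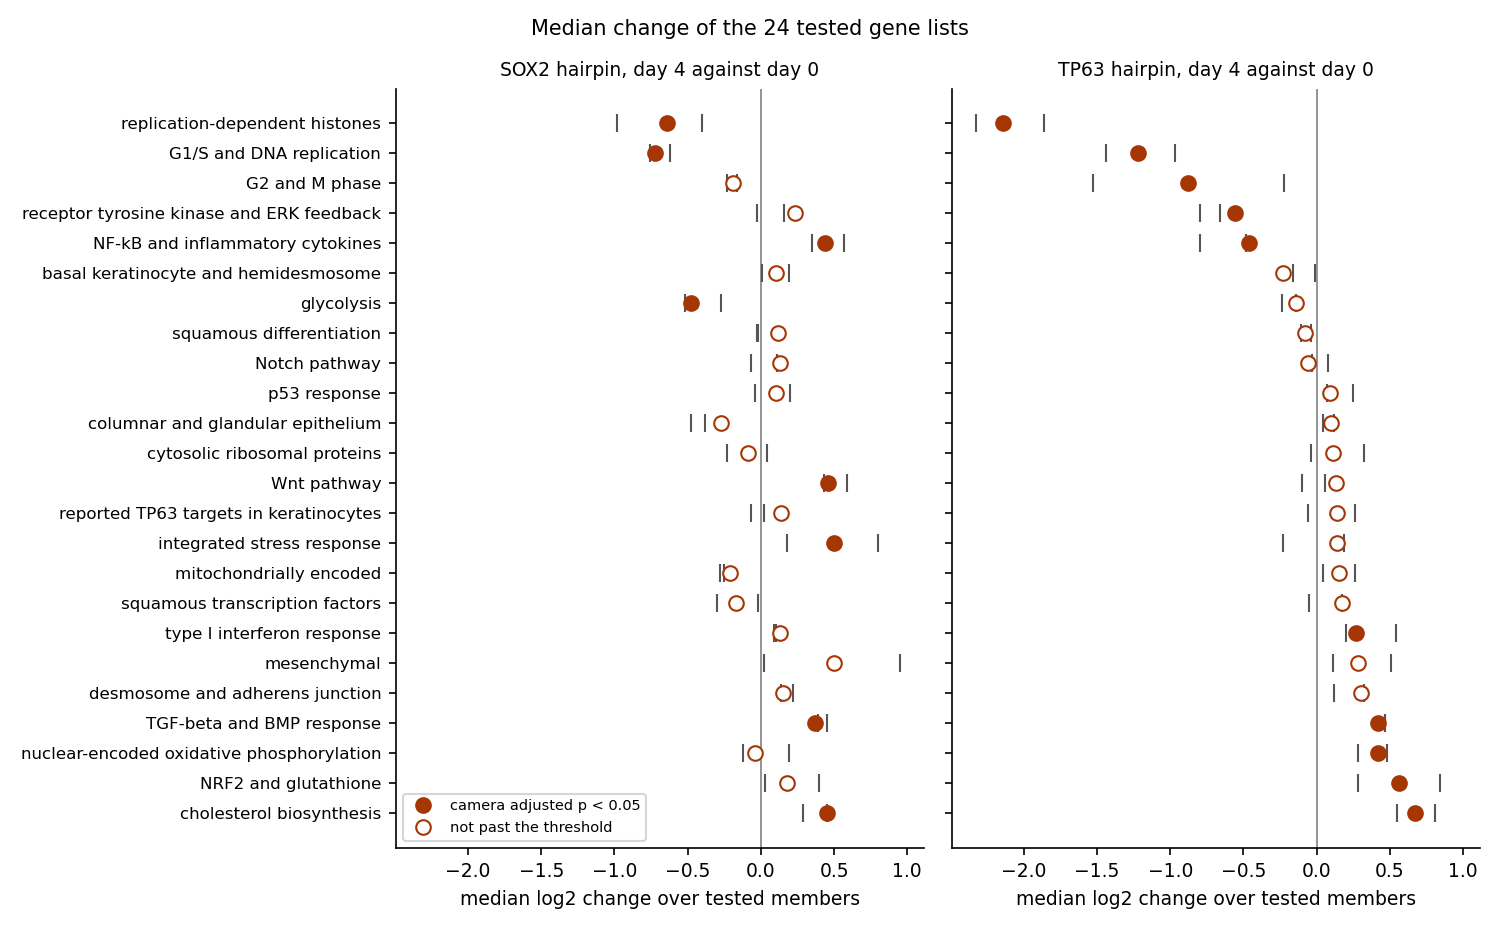
Median log2 change from day 0 to day 4 (x axis) of the tested members of each of the 24 gene lists (y axis), for the SOX2 hairpin on the left and the TP63 hairpin on the right. Large circles are medians of the fitted changes, filled where camera with a preset correlation passed, and ticks are the medians in each day 4 library. The histone median was -0.64 with the SOX2 hairpin and -2.14 with the TP63 hairpin.

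The responses to the hairpins were compared across genes. KRT6A, HK2, FOSL1 and UHRF1 were at least 2-fold lower in all 4 induced libraries, and CA11, C1S, BMP4 and COL3A1 at least 2-fold higher. By this rule of size, chosen after seeing the data because limma gave 0 and 2 calls, 63 genes were higher with both hairpins against 7.95 expected of independent lists (Fisher's exact test, two-sided, p = 1.01e-39). There were 32 lower with both against 2.93 expected (Fisher's exact test, p = 5.01e-25), and 2 and 1 genes that moved in opposite directions. Both p-values treat genes as independent, which they are not, and all changes of a line share 1 day 0 library. They therefore do not measure the spread between samples. The log2 changes had a Pearson correlation of 0.498 and a Spearman correlation of 0.488 across the 10536 genes, which are not independent replicates. Between single induced libraries of either line the Pearson correlation was 0.372 to 0.456. These contrasts share no library. There is no doxycycline-treated line with another hairpin among the samples, so the shared part cannot be assigned to the hairpins.

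**Figure D3:**
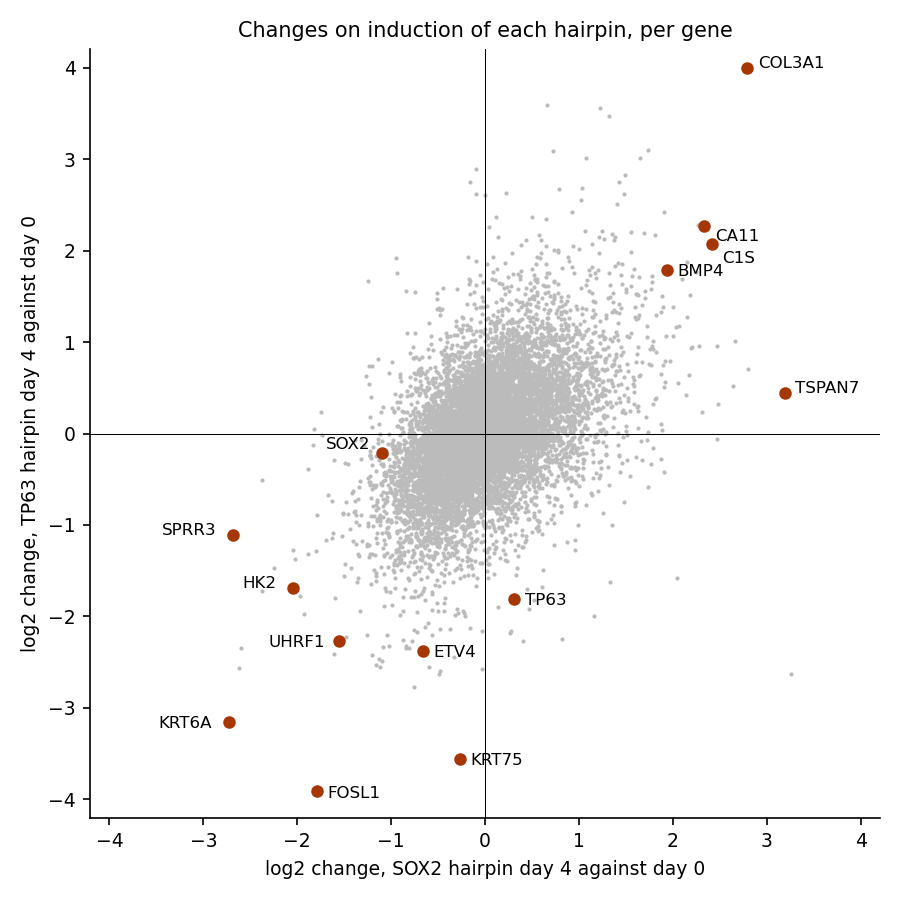
Log2 change on SOX2 hairpin induction (x axis) against log2 change on TP63 hairpin induction (y axis), 1 grey point for each of the 10536 genes tested, with named genes in colour. KRT6A lies at -2.73 and -3.15, CA11 at 2.34 and 2.27, and TP63 at 0.31 and -1.81.

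The difference between the responses was tested directly. FEZF1 had a TP63 response above its SOX2 response by a log2 difference of 2.92 ± 0.48, ARID5B by 2.26 ± 0.44, the retinal dehydrogenase gene ALDH1A1 by 2.86 ± 0.56 and the homeobox gene DLX5 by 2.29 ± 0.47. ZNF467, listed at 0 in the uninduced shTP63 library, also stood among these. KRT75 had a difference of -3.29 ± 0.55, FOSL1 one of -2.13 ± 0.45 and GNG13 one of -2.12 ± 0.41, while RNU2-6P and RMRP, structural RNA genes with near-identical copies or no poly(A) tail, were at -2.95 and -1.99. None passed. Limma called 0 of 10536 genes (smallest adjusted p = 0.962), with 479 at an unadjusted p under 0.05 against 527 expected. Without shTP63 day 4 replicate 2 limma called 5 genes, 3 higher and 2 lower. TP63 itself had a difference of -2.12 ± 0.46 and SOX2 one of 0.88 ± 0.64.

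As lists, 8 were lower and 4 higher in the TP63 response than in the SOX2 response by camera with a preset correlation. The median difference was -1.40 for histones, -1.15 for NF-kB and inflammatory cytokines, -0.66 for receptor tyrosine kinase and ERK feedback, -0.60 for G2 and M phase, -0.56 for the integrated stress response, -0.42 for G1/S and DNA replication, -0.40 for the Wnt pathway and -0.36 for basal keratinocyte and hemidesmosome genes. It was 0.63 for columnar and glandular epithelium, 0.44 for nuclear-encoded oxidative phosphorylation, 0.43 for NRF2 and glutathione and 0.24 for cytosolic ribosomal proteins. The lowest adjusted p with an estimated correlation was 0.53, so none held with it. Among members, SLC7A5 had a difference of -2.34 ± 0.55, WNT7B, a Wnt ligand gene, one of -2.39 ± 0.57, LIF one of -2.36 ± 0.62 and KRT8 one of 1.31 ± 0.45. In the NF-kB list SAA1 had a difference of -5.88 ± 1.31. The uninduced shTP63 library was above the uninduced shSOX2 library for SAA1 (4.06 against 1.07), LIF (2.15 against 1.46), TNFAIP3 (2.22 against 1.32) and IL1A (1.43 against 0.67). The size of these differences thus depends on the lone day 0 libraries. The lists that did not pass had medians from -0.55, for mesenchymal genes (camera adjusted p = 0.287), to 0.39, for cholesterol biosynthesis (0.0817). Between them lay squamous transcription factors at 0.27 (0.278), desmosome and adherens junction at 0.15 (0.494), squamous differentiation at 0.17 (0.323), the p53 response at -0.12 (0.629), type I interferon at 0.30 (0.857), Notch at -0.02 (0.653), TGF-beta and BMP at -0.03 (0.653), glycolysis at 0.28 (0.225), reported TP63 targets at 0.03 (0.857) and mitochondrially encoded genes at 0.29 (0.225). For TGF-beta and BMP the mean of 0.07 and the test were positive. Over all genes 0 members of any list passed. When adjusted over the list alone 3 NF-kB genes were lower, as were 1 gene each of the squamous transcription factors, Wnt and receptor tyrosine kinase lists, and 1 gene each of the squamous transcription factors, squamous differentiation and reported TP63 targets was higher. The lower squamous transcription factor gene was TP63, a hairpin target. CD68 had a difference of -1.46 ± 0.42. Without shTP63 day 4 replicate 2 the calls of G2 and M phase (camera adjusted p = 0.776), G1/S (0.162) and NRF2 (0.501) were lost, without shSOX2 day 4 replicate 2 those of the integrated stress response (0.0586), oxidative phosphorylation (0.0507), NRF2 (0.301) and ribosomal proteins (0.318), and without shTP63 day 4 replicate 1 those of columnar epithelium (0.126) and ribosomal proteins (0.662). Cholesterol biosynthesis (0.043) and glycolysis (0.00664) passed without shSOX2 day 4 replicate 1, cholesterol biosynthesis (0.00659) and mitochondrially encoded genes (0.00109) without shTP63 day 4 replicate 2, and squamous transcription factors (0.0474) without shTP63 day 4 replicate 1. With no filter the columnar (0.372), NRF2 (0.366) and ribosomal (0.366) calls were lost. Over 15 alternatives the NRF2 call held in 9, and the Notch list passed in 1.

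Between the induced lines, the comparison with 2 libraries on both sides, DLX5 was higher in shTP63 cells by a log2 difference of 2.65 ± 0.27 (limma adjusted p = 0.0255), ID2 by 2.80 ± 0.35, CDKN1A by 2.22 ± 0.30, FEZF1 by 2.21 ± 0.28 and ID4 by 2.18 ± 0.26. SPP1, the osteopontin gene, was lower in shTP63 cells with a difference of -3.41 ± 0.43 (limma adjusted p = 0.0326). MIR711 was lower with -2.55 ± 0.28, together with COL7A1, the anchoring fibril collagen gene it lies within, at -2.17 ± 0.27, and both can share reads. The mitochondrially encoded genes MT-ND5 and MT-ND6 were at -2.53 ± 0.23 and -2.52 ± 0.23 and the mitochondrial pseudogene MTND2P28 at -2.50 ± 0.28. The value of the pseudogene is uncertain for the same reason. Between the uninduced libraries MTND2P28 already differed by -2.52, MT-ND6 by -2.31, MT-ND5 by -2.13, COL7A1 by -1.31, MIR711 by -1.23, CDKN1A by 0.92, ID4 by 0.81, ID2 by 0.70, DLX5 by 0.37 and SPP1 by -0.34, and FEZF1 by -0.71, the other way. Limma called 80 genes, 26 higher and 54 lower in shTP63 cells, and 2424 had an unadjusted p under 0.05. This contrast also holds differences between the lines before induction. Of the 80, 73 differed in the same direction between the uninduced libraries, 32 of them at least 2-fold, and 18 were mitochondrial, structural RNA or histone genes. With such genes left out, a setting chosen after seeing the data, 16 genes were called, 7 higher and 9 lower. Without shSOX2 day 4 replicate 2, and without shSOX2 day 4 replicate 1, 0 genes were called, without shTP63 day 4 replicate 1 324, with a mean RPKM of at least 5 44, and with no filter 0.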

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

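All weighing tests in this part were chosen after their results or related values were seen; the list tests themselves were planned. Of the 24 lists tested, 12 had responses that differed between the hairpins by camera with a preset correlation. No group holds enough libraries to look for a single sample far from the others. The median differences, TP63 response minus SOX2 response, were -1.40 for replication-dependent histones (camera adjusted p = 5.4e-16), -1.15 for NF-kB and inflammatory cytokines (3.01e-06), -0.66 for receptor tyrosine kinase and ERK feedback (2.22e-05), -0.60 for G2 and M phase (0.000202), -0.56 for the integrated stress response (6.09e-05), -0.42 for G1/S and DNA replication (0.000381), -0.40 for the Wnt pathway (0.00903) and -0.36 for basal keratinocyte and hemidesmosome genes (0.00149). They were 0.63 for columnar and glandular epithelium (0.0301), 0.44 for nuclear-encoded oxidative phosphorylation (0.000331), 0.43 for NRF2 and glutathione (0.0191) and 0.24 for cytosolic ribosomal proteins (0.0301). With an estimated correlation 0 of the 12 passed (lowest adjusted p = 0.53). The size of the NF-kB difference depends on the lone day 0 libraries, where SAA1 stood at 4.06 in shTP63 and at 1.07 in shSOX2. Without shTP63 day 4 replicate 2 the calls of G2 and M phase (camera adjusted p = 0.776), G1/S (0.162) and NRF2 (0.501) were lost. Without shSOX2 day 4 replicate 2 those of the integrated stress response (0.0586), oxidative phosphorylation (0.0507), NRF2 (0.301) and ribosomal proteins (0.318) were lost, and without shTP63 day 4 replicate 1 those of columnar epithelium (0.126) and ribosomal proteins (0.662).

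The histone genes, at a median of 4.83 in the uninduced shTP63 library against 3.26 in the uninduced shSOX2 library, had the largest difference of these lists. Less carry-over of RNA without poly(A) tails would lower structural RNA genes too. On TP63 hairpin induction the 45 structural RNA genes had a median log2 change of 0.31 (SD over genes 1.05), against -2.14 for histones. As a set they did not fall, but this does not settle the point, because the change rests on the lone uninduced library. SNORA59B was at 0 there and could only rise. RMRP fell from 11.69 to 10.69 in both induced libraries, and RNU2-6P from 2.6 to 1.31 and 0.65. For the difference between the responses carry-over stays open as well. The structural RNA genes had a median of 1.04 (SD over genes 0.57) on SOX2 hairpin induction and a median difference of -0.57 (SD over genes 1.01). A high value in the lone uninduced library stays open, because the line has no other: with the uninduced shSOX2 library as the control the histone median was -0.49 (SD over genes 0.43). Induced shTP63 replicate 1, at a histone median of 3.27, did not lie below that control, and replicate 2, at 2.42, did. Fewer cells in S phase may contribute, as the G1/S list had a median of -1.20 (SD over genes 0.53) with that same control, where a value near 0 was possible. The lists did not always move together, however. The uninduced shTP63 and shSOX2 libraries had G1/S medians of 3.68 and 3.59 but histone medians of 4.83 and 3.26. Induced shTP63 replicate 1 had a lower G1/S median (2.62) than the induced shSOX2 libraries (2.95 and 2.84) but a higher histone median (3.27 against 2.91 and 2.39). In replicate 2 the G1/S median was 1.97 and the histone median 2.42.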

How the results depend on the processing

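The settings that left out shTP63 day 0, used the size rule for shared genes, or left out mitochondrial, structural RNA and histone genes were chosen after seeing the data. The cause of a change was not tested unless the setting itself shows it. Of the alternative values for the comparisons, 117 were the same, which for a count means only within 1.5 times and says nothing of which genes, 53 moved and 1 came to pass. On TP63 hairpin induction a pseudocount of 5 gave 3 calls, 0 higher and 3 lower, and ZNF467 was lost (adjusted p = 0.102). Of those for single genes and lists 4341 were the same, 158 came to pass, 150 no longer passed and 21 reversed. Quantile normalization moved almost nothing, as the deposited values already have it, so it says nothing on stability. Calls on SOX2 hairpin induction were 1 with a pseudocount of 5, 2 with both day 0 libraries as the control, 11 with the libraries of the line alone, and 0 to 11 without each day 4 library. Those on TP63 hairpin induction were 5 with a pseudocount of 0.1, 154 with no filter, 1 at a mean RPKM of at least 5, 291 with both day 0 libraries, 50 with shTP63 day 0 left out, 4 with mitochondrial, structural RNA and histone genes left out, 0 with the line alone, and 0 to 80 without each day 4 library. Between the induced lines they were 46 and 30 with pseudocounts of 0.1 and 5, 0 with no filter, 44 at a mean RPKM of at least 5, 16 with the named classes left out and 0 to 324 without each library, and for the difference 0 to 5. Genes at least 2-fold changed in both libraries numbered 685 and 93 with pseudocounts of 0.1 and 5, 878 against the other day 0 library and 748 to 1104 with 1 library for SOX2, and 1163, 182, 376 at a mean RPKM of at least 5 and 1214 to 1291 with 1 library for TP63. The TP63 change passed with both day 0 libraries as the control (-1.61). The correlation of the responses was 0.46 with no filter, 0.537 at a mean RPKM of at least 5 and 0.435 to 0.49 without each library, and 95 genes were shared by the size rule against 0 by calls. Lists passing numbered 5 at a mean RPKM of at least 5 and 7 to 13 without each library for SOX2, and 0 with an estimated correlation and 0 with fry in every contrast. With the replicate number as a block, 0 genes passed on TP63 hairpin induction, 18 between the induced lines, where the call of TP63 was lost (adjusted p = 0.0667), and 14 lists for SOX2, where cholesterol biosynthesis was lost (adjusted p = 0.0823), and the correlation of responses was 0.547. Between the day 4 groups the deviations of same-numbered libraries correlated at -0.074, so no pairing was seen there. Both day 0 libraries carry number 2 and stand alone in their groups, so pairing of day 0 with day 4 within a line was not testable. With number 2 alone at both days the change was -0.61 for SOX2 and -1.73 for TP63, each in its own line. Under the block SOX2 in the shTP63 line was 0.065. Reversals against both day 0 libraries were MT-ND6 0.327, MT-ND5 0.335, MT-ND1 1.339 and MT-ND2 1.023 for SOX2, and MT-ND1 -0.733, MT-CO1 -0.34 and the mitochondrial list -1.098 for TP63. With shTP63 day 0 left out they were KRT75 0.135, SCNN1A -0.352, SAA1 0.355, MT-ND1 -2.673, MT-CO1 -2.094, NDUFA9 -0.021, RPL32 -0.252, RPS25 -0.374, RPL23 -0.057, the mitochondrial list -2.551 and the NF-kB list 0.183. Without each shSOX2 day 4 library SOX2 between the induced lines was -0.167 to 0.811 and SCNN1A on SOX2 hairpin induction -0.198 to 0.723. Depth is unknown, and the uninduced shTP63 library, with 16167 genes above 0, limits what can be said of low genes there.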

Other observations

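Genes at least 2-fold changed in all 4 induced libraries were listed after seeing the data, ranked by the smallest of the 4 changes. On the higher side COL3A1 had log2 changes of 2.79 ± 0.88 with the SOX2 hairpin and 4.00 ± 0.88 with the TP63 hairpin, and COL5A1 of 2.15 ± 0.50 and 1.88 ± 0.50. The mesenchymal list that holds both did not pass in either line (camera adjusted p = 0.0555 and 0.602). Also higher were PBXIP1 at 1.91 ± 0.40 and 2.42 ± 0.40, METTL7A at 1.69 ± 0.40 and 2.20 ± 0.40, and MAPRE3, a microtubule end-binding gene, at 1.56 ± 0.35 and 2.20 ± 0.35. On the lower side were the keratin 6 genes, with KRT6C at -2.62 ± 0.55 and -2.56 ± 0.55, the tubulin gene TUBB4B at -1.43 ± 0.33 and -1.47 ± 0.33, KIAA1199 at -1.60 ± 0.30 and -1.80 ± 0.30, and S100A2, a basal epithelial calcium-binding protein gene, at -1.48 ± 0.66 and -2.23 ± 0.66. None of these passed limma in either line, and keratin 6 genes can share reads.

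Further genes called between the induced lines were chosen here after their values were seen. JAG1, a Notch ligand gene, was lower in shTP63 cells with a log2 difference of -2.20 ± 0.33 (limma adjusted p = 0.0465). SLC7A5 was lower with -2.32 ± 0.32, SLC3A2 with -1.75 ± 0.28, SLC1A5 with -1.93 ± 0.28 and ETV4 with -1.72 ± 0.27. ID3 was higher in shTP63 cells by 1.87 ± 0.31 and MSX2 by 2.08 ± 0.29. Between the uninduced libraries SLC3A2 already differed by -0.75, JAG1 by -0.52, SLC1A5 by -0.41, ID3 by 1.22 and MSX2 by 1.32 in the same direction, and SLC7A5 by 0.02 and ETV4 by 0. No list built from these genes was tested. These calls were lost when either shSOX2 day 4 library was left out. With both pairs intact limma called 0 genes with no filter and 18 with the replicate number as a block. A lost call does not by itself show that a difference rests on the shSOX2 day 4 pair.

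The tests in this and the next paragraph were chosen after the results were seen. Mitochondrially encoded genes were lower in the shTP63 libraries, by a median log2 difference of -2.62 at day 0 (SD over genes 0.72) and -2.32 at day 4 (SD over genes 0.27), and -2.71 and -2.38 with median-ratio scaling. Normalization between libraries is argued against as the cause, because it keeps the ranks within a library, and the median rank of these genes was 52.5 or further down in each shTP63 library and 11 or higher up in each shSOX2 library. All 8 tested genes were lower in every shTP63 library than in every shSOX2 library, as library preparation that differed by line would give. A difference between the lines themselves would give the same, and the 2 cannot be told apart because line and any such batch coincide.

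The log2 changes of the lines correlated across genes at 0.498. Reduced TP63 in the shSOX2 line, of the size in the shTP63 line, is argued against as the cause, since TP63 there had a log2 change of 0.31 ± 0.32. Reduced SOX2 in the shTP63 line, at -0.22 ± 0.45, stays open because of its error. Doxycycline or 4 days of culture may also give correlated responses, and the correlation of 0.498 cannot decide, because no line with another hairpin is among the samples. A shared program under both factors is a further hypothesis and was not tested separately.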
